A study of Mus musculus with 11 samples.

How the data were processed

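RNA sequencing of cultured splenic CD3+ T cells was analysed in 11 libraries: 5 of NZM2328 females, 3 of NZM2328 males and 3 of C57BL/6 females. Per the labels' protocols, CD3+ cells were negatively selected and cultured for 48 hours in wells coated with anti-CD3 (10 micrograms per ml) in medium with anti-CD28 (10 micrograms per ml). RNA was taken up in TRIzol, and libraries were made with a stranded polyadenylated RNA kit (TruSeq Stranded mRNA). The labels number each library within its group and do not say which libraries shared a culture day or sequencing run. The name of wild-type replicate 4 ends in an added 2, in the labels and in the count table, with no meaning given, so a repeated run is open. The p-values of edgeR measure the spread between these libraries. Those of Fisher's exact test, the permutation and the sign test count genes, which are not independent replicates.

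The deposited count table holds estimated counts per gene, with no normalization across libraries, per the file headers and the values, none of which is a whole number above 0. Per the submitters' processing notes, kallisto 0.46.0, edgeR 3.34.1, limma 3.48.3 and the builds GRCm38 and mm10 were used, with no role or order given, and the step from transcripts to genes was not given in the sources used here. Whether counting used the strand is likewise not given in the sources used here. The other deposited tables hold log2 values of selected genes made by the authors, each equal to the log2 CPM of the count table with an offset of 0.5 plus a constant per library, to within 7.3e-06; they were used only for lists of genes and directions, and how their genes were chosen is not given in the sources used here. The smallest absolute difference of group means in them was 0.486 against wild type and 0.5 against males.

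Estimated counts were rounded to whole numbers. Of 41761 entries, 39315 matched the GRCm38 annotation by symbol and 1035 by an older symbol, 1384 were not matched, and 27 were named as dates and kept in library totals with 0.184% to 0.206% of the counts. Library totals were 17083829 to 23203047 counts, with 18049 to 19775 genes having a count. A group at 0 in all libraries was set at a floor of 3 counts over the group, and a gene with 1 to 3 counts over a group was given as a ratio of summed counts with an exact binomial interval, both covering counting error only. Every pair of libraries of 1 group differed by more than sampling noise (chi-square over degrees of freedom 8.1 to 21.3 over genes with at least 20 counts), so none was treated as a duplicate.

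Before the data were examined, the design, the gene lists, the rule for named genes and most alternatives were fixed. Genes with a CPM above 1 in at least 3 libraries were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, quasi-likelihood F test, 1 fit of all 11 libraries with group as the only term, Benjamini-Hochberg adjusted p under 0.05). Log2 fold changes are those of this fit, with SE the absolute fold change over the square root of its F statistic. Gene lists were tested against all other genes with camera of limma 3.58.1 on voom weights (preset correlation 0.01, and an estimated correlation beside it), adjusted over 33 lists within a comparison. X-linked genes were compared with autosomal genes by the 2-sided Fisher's exact test with 95% intervals, adjusted over 4 tests, and by camera. The lists covered interferon-stimulated genes, X-inactivation escape genes, X-linked immune genes, Xist interactors, cytokines, activation, T helper subsets, inhibitory receptors, naive T cells, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, stress responses, apoptosis, the chromosome 1 lupus interval, histocompatibility genes, Y-linked genes, immediate early and mitochondrial genes, and markers of 13 cell types. Some genes are on more than 1 list.

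Genes were named by rule in each comparison. These were the 6 highest and 6 lowest fold changes among called genes with a mean CPM of at least 5 and no overlap between groups, leaving out receptor and immunoglobulin segments, pseudogenes and provisional names. From each list came up to 4 (first 6 lists) or 2 called members with the smallest adjusted p, or the member with the smallest p where none was called. The 5 X-linked genes with the smallest adjusted p in each direction were added, as were Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Cxcr3, Cd40lg, Tlr7, Foxp3, Il2rg and Irak1. Some genes that the rule names are not reported here. Shared sequence was measured as the percent of a gene's 31-base sequences that occur in the transcripts of another gene of the annotation. The division of reads between copies cannot be checked in the count table, so named genes that share much sequence are uncertain. These include Gvin1, mt-Nd3, Eno1b, Bcl2a1b, Bcl2a1d, Ftl1, mt-Co1, H2-Q7, Tsix, H2-DMb1, Oas1a, Lyz2, Itgam, Il12rb2, Foxp3, Il2rg, Gapdh, Ccnb1, Mid1, Pydc4, Rpl36a, Hba-a1, Hbb-bs, Hbb-bt and Tcrg-C1.

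The fit was tested on simulated counts with 200 genes changed by known folds. Against wild type, 50.7% of 1.5-fold, 77.6% of 2-fold and 89.4% of 4-fold changes were recovered among 12957 genes in the fit, and against males 56.7%, 65.7% and 92.4% among 12953. Of 152 and 148 simulated genes called, 7 and 5 were unchanged. Alternatives were DESeq2 1.42.0, limma-voom, other normalizations and filters, stricter thresholds, only the groups compared, the replicate number as a block, and each library left out. A fit with the macrophage marker level as a covariate and one restricted to protein-coding genes with little shared sequence, and the escape list without Xist, were chosen after seeing the data. NZM2328 males against wild-type females were fitted for the closing section only. Strain, age and group cannot be told apart in this design, and the design text of the series gives an age range of 18 to 24 weeks where the label of the wild-type females gives 17.5.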

Results

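Gene expression was measured by RNA sequencing in splenic CD3+ T cells of mice, isolated by negative selection and cultured for 48 hours on plate-bound anti-CD3 with soluble anti-CD28, which engage the T cell receptor and its costimulatory receptor. The 11 libraries came from 5 female and 3 male mice of NZM2328, a strain that develops lupus spontaneously and more often in females, and from 3 female C57BL/6 mice, called wild type here. The labels give an age of 22 weeks for the NZM2328 females, 23 weeks for the males and 17.5 weeks for the wild-type females. Total counts were 17083829 to 22676453 in the NZM2328 females, 19206237 to 20191395 in the males and 17806190 to 23203047 in the wild-type females. Libraries of 1 group had Spearman correlations of 0.985 to 0.992 across genes, and libraries of different groups 0.924 to 0.980. The first principal component held 60.3% of the variance and parted the wild-type from the NZM2328 libraries, and the second held 16.6% and parted the NZM2328 males from the other libraries. Xist, the RNA that coats the inactive X chromosome, had 15787 to 39942 counts in each female library and 3 to 20 in each male library. The Y-linked gene Eif2s3y had at most 2 counts in a female library and 1980 to 2050 in the male libraries. Values below are mean CPM ± SD, counts scaled to the normalized library total, over n = 5 NZM2328 female, n = 3 wild-type female or n = 3 NZM2328 male libraries, and fold changes are on the log2 scale with their standard errors (SE).

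The first comparison set activated T cells of NZM2328 females against those of wild-type females, which bears on how the lupus-prone strain differs, X-linked genes in particular. Of 46 interferon-stimulated genes 45 were higher in the NZM2328 females (adjusted p = 0.124 by camera with an estimated correlation). Irf7, a transcription factor of the type I interferon response, stood at 49.2 ± 4.59 CPM (n = 5) against 5.35 ± 0.945 CPM (n = 3), a log2 fold change of 3.20 (SE 0.13). Of 20 glycolysis genes 19 were lower (adjusted p = 0.331 by camera with an estimated correlation), with Ldha, the lactate dehydrogenase subunit, at 1012 ± 78.4 against 3396 ± 77.8 CPM, a log2 fold change of -1.75 (SE 0.06). Foxp3, the X-linked transcription factor of regulatory T cells, was at 65.4 ± 16.2 against 4.78 ± 1.08 CPM, and Il9, a T cell cytokine, at 87.3 ± 17.3 against 2.13 ± 1.24 CPM. Lyz2, the lysozyme of myeloid cells and 1 of 11 tested macrophage and monocyte markers that all rose, stood at 236 ± 86.1 against 3.57 ± 1.71 CPM.

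Of 13248 genes tested, 3856 were higher and 3484 lower in NZM2328 females, 55.4% of the genes tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among them 1771 were more than 2-fold higher and 742 more than 2-fold lower. Strain, age and any unlabelled batch part these groups together and cannot be told apart. With the macrophage marker level as a covariate, chosen after seeing the data and with 96.0% of its variance between groups, 298 genes were called, as the median SE went from 0.117 to 0.503 and the median absolute log2 fold change from 0.35 to 0.54. The authors' deposited table for this comparison lists 4301 genes, of which 4291 were tested here, all of them in the same direction, and 4240 were called.

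The largest increases and decreases given here are those the naming rule covers, among called genes with a mean CPM of at least 5. The largest such increases were in genes at or near 0 in the wild-type libraries. BC018473, an antisense gene, was at 84.5 ± 16.4 CPM, at least 1580-fold higher against a floor of 3 counts over the wild-type group, and the strand used in counting was not given in the sources used here. Ccnb1ip1, a ubiquitin ligase, was at 24.5 ± 3.67 CPM and at least 456-fold higher, and Cpt1c, a carnitine palmitoyltransferase, at 19.4 ± 7.55 CPM and at least 362-fold higher. Mtus1 had 2288 counts against 1, a ratio of 1330 with an exact counting interval of 238 to 52500. Eno1b, an enolase copy that shares 89.2% of its 31-base sequences with other genes, had 1362 ± 131 against 2.81 ± 2.02 CPM. The largest decreases included Gvin1, an interferon-inducible GTPase at 0 counts in all NZM2328 libraries and 163 ± 30.0 CPM in wild type, at least 5220-fold lower. Ftl1, the ferritin light chain, was at 0.349 ± 0.399 against 591 ± 30.2 CPM. Gvin1 shares 99.7% and Ftl1 64.1% of their 31-base sequences with other genes, so both values are uncertain, as is that of Eno1b. Htatip2 (-8.38, SE 0.59), Rbm44 (-6.69, SE 0.58), Rab6b (-6.48, SE 0.55) and Prdm16, a zinc finger transcription factor (-6.09, SE 0.44), had the other large decreases in log2 fold change.

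Of 46 interferon-stimulated genes tested, 45 rose and 1 fell (45 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 1.94. The antiviral oligoadenylate synthetase genes Oas2 (4.38, SE 0.19) and Oas1a (3.54, SE 0.11) rose with Irf7 and with Slfn5, a Schlafen family gene (2.11, SE 0.10). Oas1a shares 68.8% of its 31-base sequences with other genes and is uncertain. The interferon-stimulated list had a camera adjusted p of 2.46e-19, and adjusted p = 0.124 with an estimated correlation. The mean log2 CPM of the list was 5.22 to 5.42 in the NZM2328 female libraries and 2.82 to 3.15 in the wild-type libraries. In the same libraries the mean log2 CPM of the macrophage and monocyte markers was 2.33 to 3.80 and -1.36 to -0.64.

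**Figure D1:**
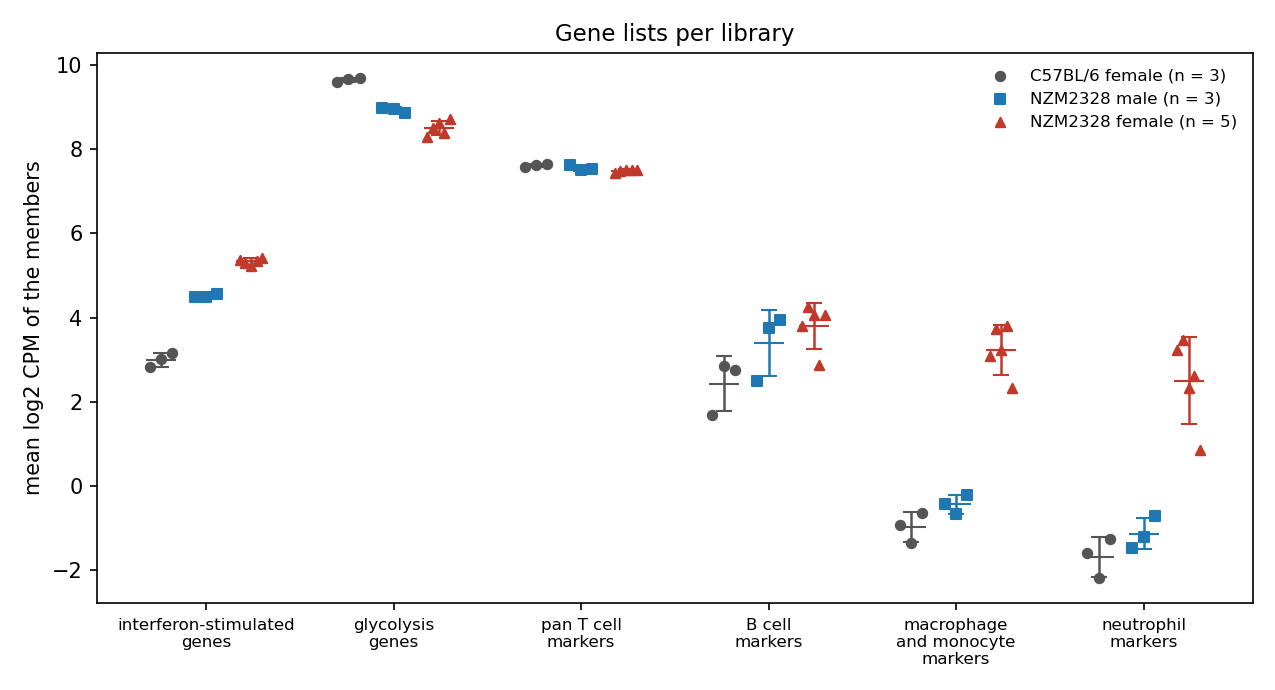
Mean log2 CPM of the members of 6 gene lists in each library; points are libraries, the horizontal bar is the group mean and the error bar its SD (n = 3, 3 and 5). The interferon-stimulated list lay at 2.82 to 3.15 in wild-type females, 4.49 to 4.57 in NZM2328 males and 5.22 to 5.42 in NZM2328 females.

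Among 29 T cell cytokine and effector genes, 20 rose, 5 fell and 4 did not pass the test (20 higher and 6 lower adjusted over the list alone). Csf2, which encodes the granulocyte-macrophage growth factor, rose by 4.17 (SE 0.16) on the log2 scale, Il9 by 5.41 (SE 0.32), Il2, the T cell growth factor, by 2.51 (SE 0.15) and Tnf by 1.60 (SE 0.06). The cytokine list had a camera adjusted p of 0.00127, and adjusted p = 0.214 with an estimated correlation. T cell activation genes went both ways: of 31, 12 rose, 11 fell and 8 did not pass the test (12 higher and 11 lower adjusted over the list alone), with a median of -0.06 (-0.012 without NZM2328 female replicate 2, -0.099 without wild-type replicate 4 and -0.105 without female replicate 5), a mean of 0.04 and a camera adjusted p of 0.936. Egr2 (2.34, SE 0.11) and Nr4a3 (2.16, SE 0.11), transcription factors induced through the T cell receptor, rose, and Batf3 fell (-1.25, SE 0.08). Ctla4, an inhibitory receptor, was at 18.4 ± 5.58 CPM in NZM2328 females, 35.7 ± 7.04 in NZM2328 males and 439 ± 47.7 in wild type. Of 27 T helper subset regulators, 11 rose, 5 fell and 11 did not pass the test (11 higher and 5 lower adjusted over the list alone), among them Foxp3 and Tbx21, the T-bet gene (1.15, SE 0.07). The T helper list had a camera adjusted p of 0.143. Of 15 inhibitory receptor and exhaustion genes, 8 rose, 3 fell and 4 did not pass the test (9 higher and 3 lower adjusted over the list alone), with Cd200 higher (1.60, SE 0.08). The inhibitory receptor list had a camera adjusted p of 0.130. Of 18 naive and resting T cell genes, 5 rose, 9 fell and 4 did not pass the test (5 higher and 9 lower adjusted over the list alone). The naive T cell list had a camera adjusted p of 0.383. Their median was -0.21, or -0.315 without wild-type replicate 1, and their mean 0.13, and Klf3 (3.23, SE 0.18) and Ccr9, a chemokine receptor (4.26, SE 0.24), rose. Macrophage and monocyte markers were higher by a median of 4.99 in the libraries where these genes moved. In the same comparison 3 of 3 CD4 T cell markers rose and 3 of 3 CD8 T cell markers fell. Whether a changed share of CD4 and CD8 T cells moved the genes of these lists was not tested.

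Of 20 glycolysis genes, 19 fell and 1 did not pass the test (1 higher and 19 lower adjusted over the list alone), with a median of -1.04, among them Ldha and Gpi1, which encodes glucose-6-phosphate isomerase (-1.49, SE 0.07). The glycolysis list had a camera adjusted p of 4.15e-11, and adjusted p = 0.331 with an estimated correlation. Eno1b shares 81.8% of its 31-base sequences with Eno1, a member of this list, so the value of Eno1 is uncertain. Of 24 oxidative phosphorylation genes, 18 fell and 6 did not pass the test (18 lower adjusted over the list alone), with a median of -0.27, including Uqcrfs1 (-0.57, SE 0.05) and Ndufa9 (-0.44, SE 0.05), subunits of the respiratory chain. The oxidative phosphorylation list had a camera adjusted p of 2.40e-05, and adjusted p = 0.214 with an estimated correlation. Of 22 cholesterol synthesis genes, 14 fell and 8 did not pass the test (15 lower adjusted over the list alone), with Hmgcs1 at -1.15 (SE 0.08) and the X-linked Nsdhl at -1.09 (SE 0.09) on the log2 scale. The cholesterol list had a camera adjusted p of 5.20e-05, and adjusted p = 0.347 with an estimated correlation. Of 38 cell cycle genes, 5 rose, 28 fell and 5 did not pass the test (5 higher and 28 lower adjusted over the list alone), and Ccnb2, a mitotic cyclin (-1.03, SE 0.06), and Cenpa, the centromeric histone (-0.90, SE 0.07), fell. The cell cycle list had a camera adjusted p of 3.70e-05, and adjusted p = 0.446 with an estimated correlation. Of 12 mitochondrially encoded genes, 3 fell and 9 did not pass the test (3 lower adjusted over the list alone). Their median was 0.04 against a mean of -0.10, and without NZM2328 female replicate 1, 2, 3, 4 or 5 it was 0.080, -0.014, 0.018, 0.12 or 0.016. The mitochondrial list had a camera adjusted p of 0.800. mt-Co1 (-1.01, SE 0.13) and mt-Nd3 (-0.88, SE 0.23) share 63.9% and 98.1% of their 31-base sequences with other genes and are uncertain. The median of the macrophage and monocyte markers was 4.99 in the same contrast.

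Of 20 unfolded protein and integrated stress response genes, 8 rose, 11 fell and 1 did not pass the test (8 higher and 11 lower adjusted over the list alone). The stress response list had a camera adjusted p of 0.155. Trib3, a pseudokinase (-2.10, SE 0.11), and Asns, the asparagine synthetase gene (-1.88, SE 0.11), fell. Of 20 apoptosis and p53 target genes, 13 rose, 2 fell and 5 did not pass the test (13 higher and 2 lower adjusted over the list alone), led by the survival genes Bcl2a1b (2.41, SE 0.09) and Bcl2a1d (2.13, SE 0.12), near-identical copies whose split is uncertain. The apoptosis list had a camera adjusted p of 0.00113, and adjusted p = 0.466 with an estimated correlation. Of 15 immediate early and heat shock genes, 8 rose, 3 fell and 4 did not pass the test (9 higher and 3 lower adjusted over the list alone), with Hsph1, a heat shock protein gene, higher (1.19, SE 0.11) and Ier3 lower (-2.17, SE 0.13). The immediate early list had a camera adjusted p of 0.130. Beside these lists the macrophage and monocyte markers had a median of 4.99 and the neutrophil markers one of 5.80.

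Of 23 genes of the lupus interval on chromosome 1, 18 rose, 3 fell and 2 did not pass the test (18 higher and 3 lower adjusted over the list alone), with a median of 2.70. Slamf7, a receptor of the SLAM family, fell from 204 ± 14.6 CPM in wild type to 57 ± 3.94 CPM, and Pydc4, the older symbol of the interferon-inducible Ifi213, rose (4.59, SE 0.26). The chromosome 1 interval list had a camera adjusted p of 0.00113, and adjusted p = 0.331 with an estimated correlation. Of 24 major histocompatibility complex genes, 20 rose, 1 fell and 3 did not pass the test (20 higher and 1 lower adjusted over the list alone), with a median of 0.74. The histocompatibility list had a camera adjusted p of 1.78e-07, and adjusted p = 0.256 with an estimated correlation. H2-T24 rose (2.18, SE 0.08) and H2-Q7 fell (-2.99, SE 0.08), both class I genes, of which H2-Q7 shares 39.2% of its 31-base sequences with other genes and is uncertain. H2-Ea-ps, chosen after its values were seen, was at 109 ± 17.6 CPM in NZM2328 females, 32.0 ± 11.8 CPM in NZM2328 males and 0 in all wild-type libraries, at least 2020-fold higher than wild type. Both lists moved beside a median of 4.99 for the macrophage and monocyte markers, and such cells also express class II and Fc receptor genes.

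Markers of cells other than T cells were measured because the culture began from a negative selection. Markers near 0 in wild type and males, such as Prss34, passed the CPM filter only through the NZM2328 females. Listed markers below the filter were not tested, with 12 listed and 11 tested for macrophages and monocytes, and 10 and 8 for neutrophils. It was 10 and 7 for dendritic cells, 6 and 4 for platelets and 10 and 5 for erythroid cells, so the filter partly set how many rose. Of 11 macrophage and monocyte markers, 11 rose (11 higher adjusted over the list alone), with a median of 4.99. The macrophage and monocyte list had a camera adjusted p of 1.92e-04, and adjusted p = 0.446 with an estimated correlation. Lyz2 (6.08, SE 0.45) and Itgam (3.92, SE 0.39) share 32.8% and 68.3% of their 31-base sequences with other genes. Of 8 neutrophil markers, 7 rose and 1 did not pass the test (7 higher adjusted over the list alone), with S100a9 (6.80, SE 0.78) and S100a8 (6.23, SE 0.81) higher. The median was 5.80, or 5.67 with the genes at 0 in wild type set at their bound, and without wild-type replicate 1 or 3 its camera adjusted p was 0.0548 to 0.0566. The neutrophil list had a camera adjusted p of 0.0370, and adjusted p = 0.503 with an estimated correlation. Of 7 mast cell and basophil markers, 7 rose (7 higher adjusted over the list alone), among them the protease gene Prss34 (7.0, SE 0.69) and Ms4a2 (4.07, SE 0.49). The mast cell list had a camera adjusted p of 0.0128, and adjusted p = 0.357 with an estimated correlation. Of 4 platelet and megakaryocyte markers, 4 rose (4 higher adjusted over the list alone), with Pf4 at 3.95 (SE 0.33). The platelet list had a camera adjusted p of 0.0279, and adjusted p = 0.466 with an estimated correlation. Of 7 dendritic cell markers, 6 rose and 1 did not pass the test (6 higher adjusted over the list alone), including Ccr9 and the interferon-inducible Bst2 (1.56, SE 0.08). The dendritic cell list had a camera adjusted p of 0.00237, and adjusted p = 0.214 with an estimated correlation.

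Of 12 B cell markers, 8 rose and 4 did not pass the test (8 higher adjusted over the list alone), with Ms4a1 (3.37, SE 0.54) and Ighm (1.48, SE 0.33) higher and a camera adjusted p of 0.0635. Without NZM2328 female replicate 4 or male replicate 1 or 3 the camera adjusted p of the B cell list was 0.0139 to 0.0493. Of 5 plasma cell markers, 4 rose and 1 did not pass the test (4 higher adjusted over the list alone), with Sdc1 at 1.27 (SE 0.17) and Igj, the older symbol of Jchain, at 3.62 (SE 0.62). The plasma cell list had a camera adjusted p of 0.130. Of 9 NK cell markers, 5 rose, 3 fell and 1 did not pass the test (5 higher and 3 lower adjusted over the list alone), with Eomes (2.23, SE 0.24) and Klrb1c (2.97, SE 0.36) higher. The NK cell list had a camera adjusted p of 0.578. Of 5 erythroid markers, 2 rose and 3 did not pass the test (2 higher adjusted over the list alone), and the globin genes Hba-a1 (4.18, SE 0.47) and Hbb-bs (3.98, SE 0.62) are near-identical to other globin genes and uncertain. The erythroid list had a camera adjusted p of 0.130. Of 12 pan T cell markers, 2 rose, 6 fell and 4 did not pass the test (2 higher and 7 lower adjusted over the list alone), with Cd3d lower (-0.70, SE 0.06) and Trac higher (1.18, SE 0.11). The pan T cell list had a camera adjusted p of 0.138. Of 3 CD4 T cell markers, 3 rose (3 higher adjusted over the list alone), Cd4 being at 429 ± 18.0 against 210.1 ± 49.2 CPM and the X-linked Cd40lg at 35.1 ± 6.53 against 8.22 ± 1.90 CPM. Of 3 CD8 T cell markers, 3 fell (3 lower adjusted over the list alone), Cd8b1 being at 68.7 ± 22.4 against 173 ± 13.8 CPM and Runx3 at 140.1 ± 12.3 against 234 ± 9.51 CPM. The camera adjusted p was 0.0225 for the CD4 and 0.0174 for the CD8 markers, and adjusted p = 0.347 for each with an estimated correlation. Of 4 gamma-delta T cell markers, 3 rose and 1 fell (3 higher and 1 lower adjusted over the list alone), with Tcrg-C4 (1.06, SE 0.28) and Tcrg-C1 (1.14, SE 0.26) higher, the latter sharing 51% of its 31-base sequences with other genes. The gamma-delta list had a camera adjusted p of 0.423.

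**Figure D2:**
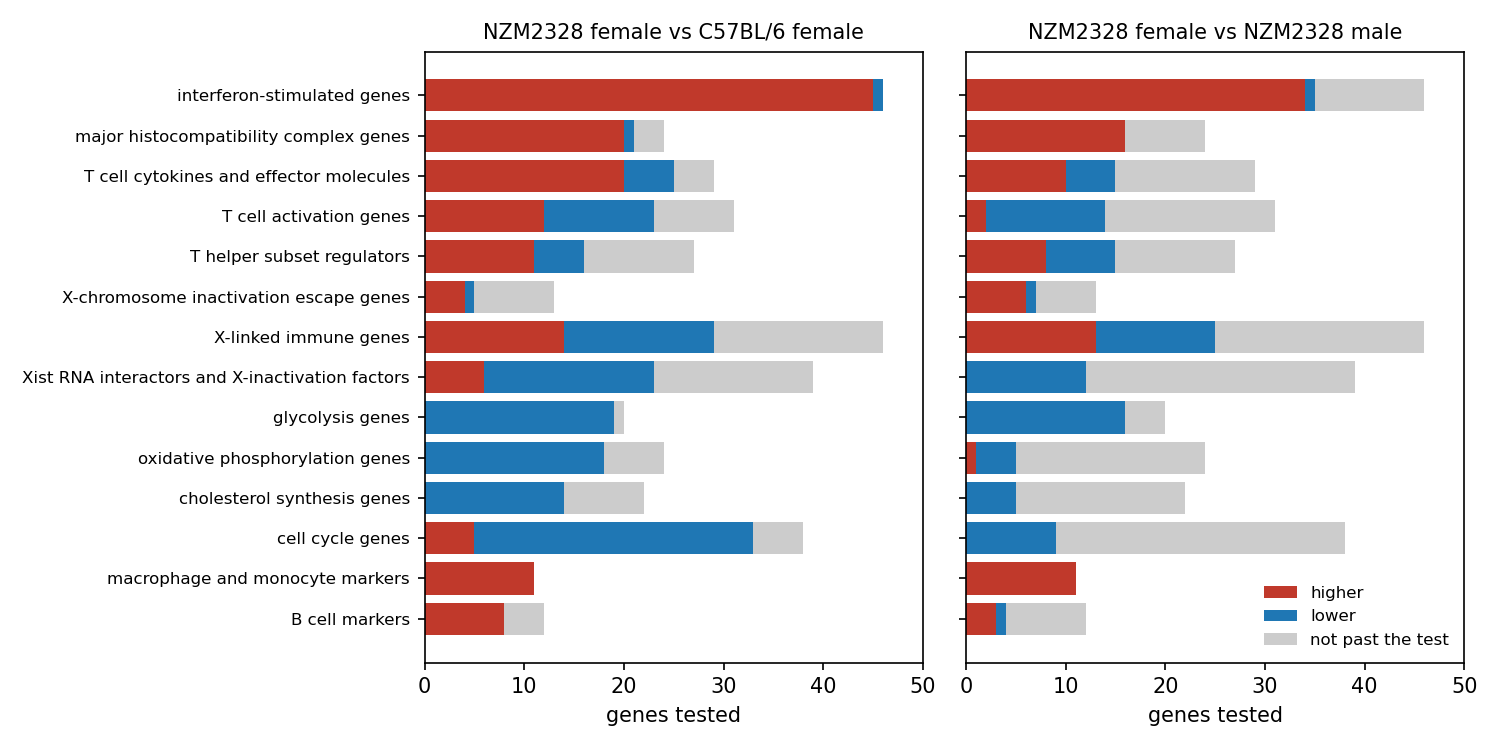
Members of 14 gene lists that were higher, lower or not past the test (adjusted p under 0.05) in each comparison of NZM2328 females; bars are counts of genes tested. In the comparison with wild type, 45 of 46 interferon-stimulated genes were higher and 19 of 20 glycolysis genes lower.

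X-linked genes were asked about because the title of the series concerns the maintenance of X-chromosome inactivation in T cells of female mice. Foxp3 (GRCm38 chromosome X, 7573644 to 7595245) rose by 3.76 (SE 0.22) on the log2 scale, Cfp, the complement factor properdin (chromosome X, 20925454 to 20931555), by 3.30 (SE 0.26), and Cd40lg, a costimulatory ligand (chromosome X, 57212143 to 57224042), by 2.10 (SE 0.19). Slc9a7, a sodium and proton exchanger (2.14, SE 0.20), Fam120c (1.38, SE 0.10) and Tlr7, an endosomal receptor for RNA (2.33, SE 0.29), also rose, and Il2rg, the common cytokine receptor chain, rose by 0.40 (SE 0.05). Pim2, a kinase gene (chromosome X, 7878262 to 7883432), fell from 499 ± 16.3 to 142 ± 9.69 CPM, and Armcx4 (-3.96, SE 0.16), Chm (-1.59, SE 0.10), Rbm3, a cold-inducible RNA-binding protein gene (-1.27, SE 0.06), Rpl36a (-0.72, SE 0.04) and the lymphocyte adaptor gene Sash3 (-0.71, SE 0.05) fell. The differences of Cxcr3, a chemokine receptor (-0.28, SE 0.15), and Irak1, a kinase downstream of Toll-like receptors (0.09, SE 0.07), did not pass the test, and without NZM2328 female replicate 4 the adjusted p of Cxcr3 by edgeR was 0.0483. Xist was at 1741 ± 189 CPM in NZM2328 females and 1538 ± 572 CPM in wild-type females (edgeR's adjusted p = 0.507).

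Of 443 X-linked genes tested, 102 (23.0%) were higher and 131 (29.6%) lower in NZM2328 females, against 29.3% and 26.3% of 12624 autosomal genes. The exact tests that follow count genes, which are not independent replicates. X-linked genes were less often among the higher genes (odds ratio 0.721, 95% interval 0.571 to 0.906, 2-sided Fisher's exact test p = 0.00401, adjusted p = 0.00803 over 4 such tests). This call was lost among genes with little shared sequence (odds ratio 0.892, exact p = 0.402) and among changes over 2-fold (0.868, exact p = 0.392). Among the lower genes the odds ratio was 1.18 (0.948 to 1.45, Fisher's exact p = 0.125, adjusted p = 0.167), with no filter on low counts 0.820 (exact p = 0.0337), and without wild-type replicate 4 it was 1.303 (exact p = 0.0157). The median log2 fold change of X-linked genes was -0.07 relative to that of autosomal genes, which camera did not separate from 0 (p = 0.195, and p = 0.316 with an estimated correlation).

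Of 13 genes listed as escaping X inactivation, 4 rose, 1 fell and 8 did not pass the test (3 higher and 1 lower adjusted over the list alone). The escape list had a camera adjusted p of 0.538. Kdm6a, a histone demethylase gene (chromosome X, 18162575 to 18279936), was at 73.9 ± 7.05 against 34.9 ± 5.95 CPM, a log2 fold change of 1.08 (SE 0.11). Shroom4 (3.08, SE 0.73) and Ftx, a noncoding RNA of the X-inactivation centre (0.58, SE 0.14), rose, and Mid1 fell (-1.20, SE 0.31), a call lost without wild-type replicate 1 (adjusted p = 0.0531 by the same edgeR test). Of 46 X-linked immune genes, 14 rose, 15 fell and 17 did not pass the test (14 higher and 15 lower adjusted over the list alone), with a median of -0.02, a mean of 0.40 and a camera adjusted p of 0.848. Upper-quartile scaling turned the median to 0.00120, and leaving out 1 library gave -0.060 (wild-type replicate 4) to 0.013 (wild-type replicate 3), also above 0 without NZM2328 female replicate 5 (0.00144). Of 39 Xist RNA interactors and X-inactivation factors, 6 rose, 17 fell and 16 did not pass the test (6 higher and 17 lower adjusted over the list alone). The Xist interactor list had a camera adjusted p of 0.130. The cohesin genes Rad21 (-0.54, SE 0.06) and Smc3 (-0.43, SE 0.05) and the deacetylase gene Hdac3 (-0.41, SE 0.04) fell, and Setdb1, a histone methyltransferase gene, rose (0.65, SE 0.05). Beside these lists the macrophage and monocyte markers had a median of 4.99, and Cfp and Tlr7 are genes that myeloid cells express. Among the NZM2328 females, however, Tlr7 was lowest in replicate 4 (10.6 CPM). That library had the highest mean log2 CPM of the macrophage and monocyte markers (3.80) and the lowest of the B cell markers (2.87). Which cells the Tlr7 reads came from was not tested. Cd40lg is also on the list of CD4 T cell markers, which rose.

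**Figure D3:**
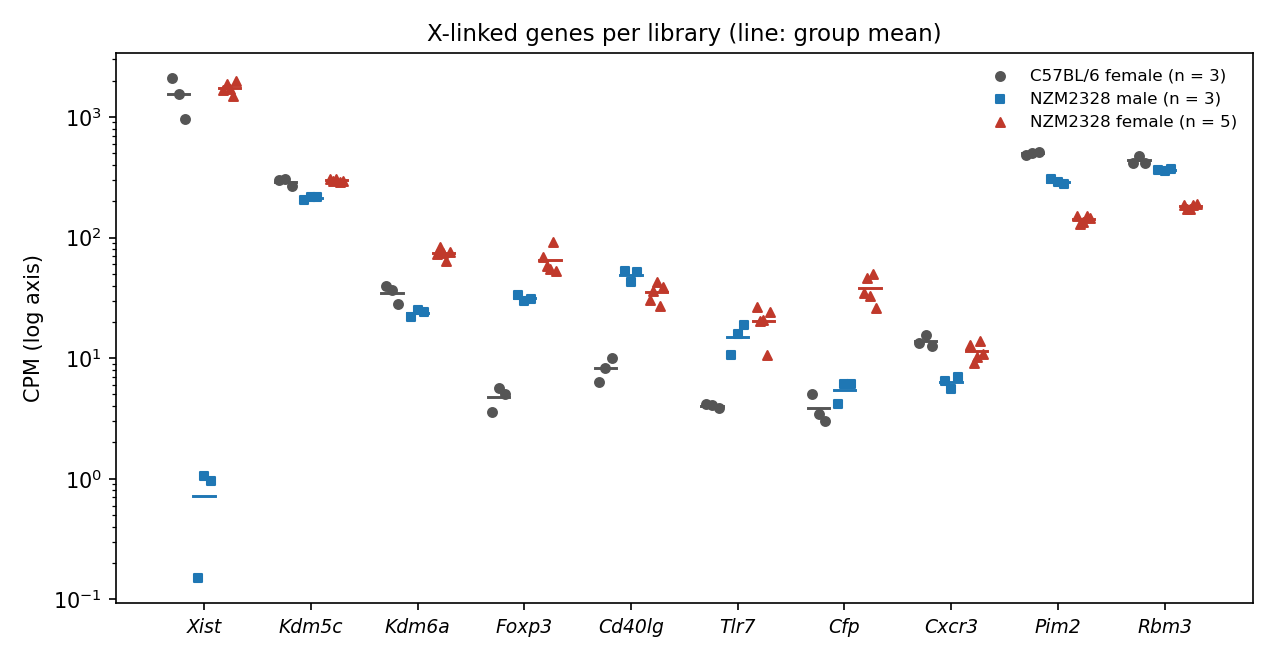
CPM of 10 X-linked genes in each library on a log axis; points are libraries and lines are group means (n = 3, 3 and 5). Xist lay at 1538 ± 572 CPM in wild-type females, 1741 ± 189 CPM in NZM2328 females and 0.722 ± 0.498 CPM in males.

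The second comparison set NZM2328 females against NZM2328 males, which share the strain and differ in sex and in the frequency of disease. The groups also differ in labelled age, 22 weeks in females and 23 weeks in males. Sex, age and any unlabelled batch cannot be told apart between them. Xist was at 1741 ± 189 CPM in females (n = 5) and 0.722 ± 0.498 CPM in males (n = 3). Other increases in females included Mmp12, the macrophage elastase, at 132 ± 57 against 2.24 ± 0.517 CPM, Epx, the eosinophil peroxidase, at 28.8 ± 16.0 against 0.235 ± 0.174 CPM, and Lyz2 at 236 ± 86.1 against 8.05 ± 1.58 CPM. Of 46 interferon-stimulated genes 34 were higher in females (adjusted p = 0.147 by camera with an estimated correlation), with Irf7 at 49.2 ± 4.59 against 23.7 ± 1.54 CPM, beside a median of 4.15 for the macrophage and monocyte markers. Il2 was lower, at 28.5 ± 4.56 against 76.1 ± 5.80 CPM, and so were Icos, a costimulatory receptor, at 603 ± 91.9 against 1351 ± 55.7 CPM, and Gzmb, the granzyme B gene, at 923 ± 253 against 2187 ± 172 CPM.

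Of 13248 genes, 2027 were higher and 1516 lower in females than in males, 26.7% of the genes tested (edgeR's quasi-likelihood test, adjusted p under 0.05), 931 of them more than 2-fold higher and 122 more than 2-fold lower. The share higher among the changed genes was 57.2%. The authors' deposited table for this comparison lists 1906 genes, of which 1901 were tested, all in the same direction, and 1748 were called. With the macrophage marker level as a covariate, chosen after seeing the data and with 96.0% of its variance between groups, 3 genes were called, as the median SE went from 0.116 to 0.440 and the median absolute log2 fold change from 0.20 to 0.35. The largest changes given here are those the naming rule covers, among called genes with a mean CPM of at least 5. Beyond Xist, the largest such increases were in Epx (6.88, SE 0.80), Tsix (6.69, SE 0.31) and Mgl2, a macrophage lectin (6.27, SE 0.54). Mmp12 (5.88, SE 0.61) and Prg2, the eosinophil major basic protein (5.58, SE 0.71), followed. Tsix is antisense to Xist and shares 34.5% of its 31-base sequences with other genes, 34.4% with Xist itself. The strand used in counting was not given in the sources used here. Whether Xist reads were counted to Tsix cannot be checked, so the Tsix value is uncertain. The largest decreases under the same rule were in the Y-linked genes and in Selp, the P-selectin gene (-2.31, SE 0.27), and Trib3 (-2.12, SE 0.11). Eif2s3y had 2 counts in the females against 6034 in the males, a ratio of 4940 with an exact counting interval of 1370 to 40800. All 4 Y-linked genes tested fell (4 lower adjusted over the list alone), with log2 fold changes of -6.58 (SE 0.49) for Ddx3y, -3.38 (SE 0.15) for Kdm5d and -3.26 (SE 0.22) for Uty. Their camera adjusted p was 2.07e-07, and adjusted p = 0.0287 with an estimated correlation. Against wild-type females, Kdm5d had 4.37 ± 0.827 and 8.12 ± 0.618 CPM and Uty 1.74 ± 0.536 and 0.652 ± 0.130 CPM in these female libraries, and of 4 Y-linked genes 1 rose, 1 fell and 2 did not pass the test (1 higher and 1 lower adjusted over the list alone). The Y-linked list had a camera adjusted p of 0.992. Both of these groups are female, so their Kdm5d and Uty reads are not expression of a Y chromosome, and the source of the reads was not tested.

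Of 46 interferon-stimulated genes, 34 rose, 1 fell and 11 did not pass the test (36 higher and 2 lower adjusted over the list alone), with a median of 0.62. Oas2 (2.01, SE 0.15), Slfn5 (1.29, SE 0.09), Oas1a (1.11, SE 0.09) and Irf7 (1.05, SE 0.11) rose. The interferon-stimulated list had a camera adjusted p of 1.20e-13, and adjusted p = 0.147 with an estimated correlation. The mean log2 CPM of the list was 4.49 to 4.57 in the male libraries, and that of the macrophage and monocyte markers -0.66 to -0.21. Of 24 major histocompatibility complex genes, 16 rose and 8 did not pass the test (16 higher adjusted over the list alone), including the class II chaperone genes H2-DMa (1.32, SE 0.12) and H2-DMb1 (2.07, SE 0.22), the latter sharing 31.4% of its 31-base sequences with H2-DMb2. The histocompatibility list had a camera adjusted p of 1.63e-07, and adjusted p = 0.225 with an estimated correlation. Of 23 genes of the chromosome 1 interval, 12 rose, 3 fell and 8 did not pass the test (13 higher and 4 lower adjusted over the list alone), with the inhibitory Fc receptor gene Fcgr2b higher (4.17, SE 0.35) and Slamf7 lower (-1.62, SE 0.07). The chromosome 1 interval list had a camera adjusted p of 0.0150, and adjusted p = 0.321 with an estimated correlation. The median of the macrophage and monocyte markers beside these lists was 4.15.

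Of 31 T cell activation genes, 2 rose, 12 fell and 17 did not pass the test (2 higher and 13 lower adjusted over the list alone), and Icos (-1.16, SE 0.11), Il2ra, the interleukin 2 receptor alpha chain (-0.58, SE 0.08), Rel (-0.47, SE 0.05) and Nfkbid (-0.47, SE 0.06), both of the NF-kappaB pathway, fell. The activation list had a camera adjusted p of 0.00353, and adjusted p = 0.225 with an estimated correlation. Of 29 cytokine and effector genes, 10 rose, 5 fell and 14 did not pass the test (10 higher and 6 lower adjusted over the list alone); Il2 (-1.42, SE 0.12) and Gzmb (-1.24, SE 0.19) fell, and Il5, an eosinophil growth factor (1.41, SE 0.21), and Ltb (0.83, SE 0.12) rose. The cytokine list had a camera adjusted p of 0.792. Of 27 T helper subset regulators, 8 rose, 7 fell and 12 did not pass the test (10 higher and 7 lower adjusted over the list alone), with Il1rl1, the interleukin 33 receptor (2.69, SE 0.27), higher and Il12rb2 (-1.25, SE 0.16) lower. The T helper list had a camera adjusted p of 0.657. Of 15 inhibitory receptor and exhaustion genes, 5 rose, 5 fell and 5 did not pass the test (5 higher and 5 lower adjusted over the list alone), with Btla at -0.89 (SE 0.11) and 4632428N05Rik, the older symbol of Vsir, at 0.64 (SE 0.13). The inhibitory receptor list had a camera adjusted p of 0.626. Of 18 naive and resting T cell genes, 8 rose, 6 fell and 4 did not pass the test (8 higher and 7 lower adjusted over the list alone), with S1pr1 at 1.44 (SE 0.11) and Ccr9 at 4.68 (SE 0.25); their median was -0.09 (-0.15 without male replicate 2, -0.021 without male replicate 1 and -0.055 without female replicate 1), their mean 0.36 and their camera adjusted p 1.00. Of 12 pan T cell markers, 3 rose, 2 fell and 7 did not pass the test (3 higher and 2 lower adjusted over the list alone), including Cd5 (-0.74, SE 0.07) and Cd2 (-0.49, SE 0.08). The pan T cell list had a camera adjusted p of 0.388. Of 3 CD4 markers, 1 fell and 2 did not pass the test (1 lower adjusted over the list alone); of 3 CD8 markers, 3 did not pass the test (no member adjusted over the list alone), with Cd8b1 at -0.25 (SE 0.20), whose adjusted p by edgeR was 0.022 without NZM2328 female replicate 4. The CD4 list had a camera adjusted p of 0.969. The CD8 list had a camera adjusted p of 0.867. Of 4 gamma-delta T cell markers, 3 rose and 1 did not pass the test (3 higher adjusted over the list alone), with Tcrg-C1 (3.30, SE 0.31) and Tcrg-C4 (2.61, SE 0.31). The gamma-delta list had a camera adjusted p of 0.0107, and adjusted p = 0.225 with an estimated correlation. In this contrast the macrophage and monocyte markers had a median of 4.15.

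Of 20 glycolysis genes, 16 fell and 4 did not pass the test (17 lower adjusted over the list alone), with Ldha at -0.53 (SE 0.06) and Gapdh at -0.45 (SE 0.06). The glycolysis list had a camera adjusted p of 5.92e-09, and adjusted p = 0.242 with an estimated correlation. Its member Eno1 is uncertain here too, through the sequence it shares with Eno1b. Of 38 cell cycle genes, 9 fell and 29 did not pass the test (8 lower adjusted over the list alone), among them Ccnb1 (-0.34, SE 0.07) and Tpx2 (-0.23, SE 0.05). The cell cycle list had a camera adjusted p of 1.95e-04, and adjusted p = 0.370 with an estimated correlation. Of 20 unfolded protein and integrated stress response genes, 4 rose, 11 fell and 5 did not pass the test (4 higher and 11 lower adjusted over the list alone), and the transcription factor gene Atf4 (-0.56, SE 0.05) and Trib3 fell. The stress response list had a camera adjusted p of 0.00315, and adjusted p = 0.242 with an estimated correlation. Of 22 cholesterol synthesis genes, 5 fell and 17 did not pass the test (5 lower adjusted over the list alone), with Hmgcs1 (-0.30, SE 0.08) lower. The cholesterol list had a camera adjusted p of 0.0371, and adjusted p = 0.550 with an estimated correlation. Of 24 oxidative phosphorylation genes, 1 rose, 4 fell and 19 did not pass the test (1 higher and 4 lower adjusted over the list alone), including Uqcrfs1 (-0.28, SE 0.05) and Atp5b (-0.20, SE 0.04). The oxidative phosphorylation list had a camera adjusted p of 0.0710. Of 15 immediate early and heat shock genes, 1 rose, 3 fell and 11 did not pass the test (1 higher and 3 lower adjusted over the list alone), with Fos (-0.77, SE 0.13) and Ier3 (-0.65, SE 0.14) lower. The immediate early list had a camera adjusted p of 0.0379, and adjusted p = 0.321 with an estimated correlation. Of 20 apoptosis and p53 target genes, 5 rose, 2 fell and 13 did not pass the test (7 higher and 2 lower adjusted over the list alone), with Bcl2l1 at -0.28 (SE 0.06) and Trp53inp1 at 0.77 (SE 0.18). The apoptosis list had a camera adjusted p of 0.0673. Of 12 mitochondrially encoded genes, 1 fell and 11 did not pass the test (1 lower adjusted over the list alone), mt-Co1 (-0.49, SE 0.13). The mitochondrial list had a camera adjusted p of 0.0673. Leaving out 1 library moved some of these calls past the threshold or back. Camera's adjusted p rose to 0.0648 to 0.107 for the cholesterol list without NZM2328 female replicate 2 or 4 or male replicate 1, and to 0.0507 to 0.0717 for the immediate early list without female replicate 1 or 2 or male replicate 1. It fell to 0.0314 for oxidative phosphorylation without female replicate 1, to 0.0193 to 0.0234 for apoptosis without female replicate 1 or 5, and to 0.0137 to 0.0416 for the mitochondrial list without female replicate 2 or 3 or male replicate 2. By edgeR, Hmgcs1 had an adjusted p of 0.0531 to 0.0589 without any 1 male library, and mt-Co1 0.0501 to 0.0865 without male replicate 1 or 3. The median of the macrophage and monocyte markers was 4.15 in the same contrast.

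Of 11 macrophage and monocyte markers, 11 rose (11 higher adjusted over the list alone), with Itgam at 3.64 (SE 0.38). As against wild type, the filter partly set such counts, since markers near 0 in males were tested through the females. The macrophage and monocyte list had a camera adjusted p of 1.49e-07, and adjusted p = 0.242 with an estimated correlation. Of 8 neutrophil markers, 8 rose (8 higher adjusted over the list alone), with S100a9 at 4.74 (SE 0.64) and S100a8 at 4.41 (SE 0.68). The neutrophil list had a camera adjusted p of 0.00178, and adjusted p = 0.321 with an estimated correlation. Of 7 dendritic cell markers, 4 rose and 3 did not pass the test (4 higher adjusted over the list alone), with Itgax at 3.64 (SE 0.32). The dendritic cell list had a camera adjusted p of 0.00315, and adjusted p = 0.225 with an estimated correlation. Of 7 mast cell and basophil markers, 6 rose and 1 did not pass the test (6 higher adjusted over the list alone), with Prss34 at 5.09 (SE 0.57) and Ms4a2 at 2.52 (SE 0.43). The mast cell list had a camera adjusted p of 0.00131, and adjusted p = 0.242 with an estimated correlation. Of 4 platelet and megakaryocyte markers, 3 rose and 1 did not pass the test (3 higher adjusted over the list alone), with Pf4 at 2.33 (SE 0.28) and Itga2b at 1.55 (SE 0.29). The platelet list had a camera adjusted p of 0.0107, and adjusted p = 0.321 with an estimated correlation. Of 9 NK cell markers, 5 rose and 4 did not pass the test (5 higher adjusted over the list alone), with Eomes at 1.61 (SE 0.23) and Klre1 at 1.34 (SE 0.30). The NK cell list had a camera adjusted p of 0.0150, and adjusted p = 0.321 with an estimated correlation. Of 12 B cell markers, 3 rose, 1 fell and 8 did not pass the test (3 higher and 1 lower adjusted over the list alone), with Cd79b at 0.95 (SE 0.27) and Fcer2a at -1.54 (SE 0.40), and of 5 plasma cell markers, 2 rose and 3 did not pass the test (2 higher adjusted over the list alone), with Xbp1 at 0.41 (SE 0.07) and Igj at 2.02 (SE 0.54). The B cell list had a camera adjusted p of 0.176. The plasma cell list had a camera adjusted p of 0.0673. Of 5 erythroid markers, 2 rose and 3 did not pass the test (3 higher adjusted over the list alone), with Klf1 at 1.87 (SE 0.56) and Hbb-bt at 1.35 (SE 0.37). The erythroid list had a camera adjusted p of 0.0379, and adjusted p = 0.417 with an estimated correlation. Without female replicate 1, 2 or 4 or male replicate 2, camera's adjusted p of the erythroid list was 0.0674 to 0.108. It was 0.0231 to 0.0445 for the B cell list without female replicate 4 or male replicate 3, and 0.0239 to 0.0408 for the plasma cell list without female replicate 1 or 4 or male replicate 3. By edgeR, adjusted p was 0.0591 to 0.0893 for Fcer2a and 0.0987 to 0.107 for Klf1 without male replicate 2 or 3, 0.0647 to 0.0731 for Igj without male replicate 1 or 2, 0.0887 for Cd79b without male replicate 1 and 0.0798 for Hbb-bt without male replicate 2.

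Of the 443 X-linked genes, 64 (14.4%) were higher and 71 (16.0%) lower in females than in males, against 15.4% and 11.3% of autosomal genes. Besides Xist and Tsix, the genes with the smallest adjusted p among those higher were Kdm6a (73.9 ± 7.05 against 23.8 ± 1.68 CPM), Cfp (2.79, SE 0.25) and Kdm5c, a histone demethylase gene (0.49, SE 0.05), and those lower were Rbm3 (-1.01, SE 0.06), Pim2 (-1.03, SE 0.06), the amino acid transporter gene Slc7a3 (-1.61, SE 0.16), Itm2a (-0.75, SE 0.08) and Chm (-0.76, SE 0.10). X-linked genes were more often among the lower genes (odds ratio 1.498, 95% interval 1.14 to 1.95, 2-sided Fisher's exact p = 0.00305, adjusted p = 0.00803). Among genes with little shared sequence this odds ratio was 1.28 (exact p = 0.117), among changes over 2-fold 1.88 (exact p = 0.112), with no filter on low counts 0.995 (exact p = 1). Among the higher genes the odds ratio was 0.931 (0.699 to 1.22, Fisher's exact p = 0.639, adjusted p = 0.639). These exact tests likewise count genes that are not independent. The median of X-linked minus autosomal fold changes was -0.04 (camera p = 0.383, and p = 0.492 with an estimated correlation), or -0.019 without NZM2328 female replicate 4 and -0.020 without male replicate 3. Of 13 escape genes, 6 rose, 1 fell and 6 did not pass the test (8 higher and 1 lower adjusted over the list alone), with a median of 0.51, a mean of 1.37 that includes Xist itself, and Pbdc1 at 0.51 (SE 0.06). The escape list had a camera adjusted p of 0.00142, and adjusted p = 0.242 with an estimated correlation. Without Xist, a choice made after seeing the data, its mean was 0.54 and its camera adjusted p 0.00433, and adjusted p = 0.272 with an estimated correlation. Of 46 X-linked immune genes, 13 rose, 12 fell and 21 did not pass the test (15 higher and 14 lower adjusted over the list alone), including Cybb, a subunit of the phagocyte oxidase (2.02, SE 0.26), Foxp3 (1.06, SE 0.18) and Cxcr3 (0.85, SE 0.16), which rose. The X-linked immune list had a camera adjusted p of 0.867. Cd40lg fell (-0.48, SE 0.16), a call lost without wild-type replicate 3, NZM2328 female replicate 1, 2 or 4, or any 1 male library (edgeR adjusted p 0.0545 to 0.158), while Tlr7 (0.44, SE 0.26), Il2rg (0.03, SE 0.05) and Irak1 (0.06, SE 0.07) did not pass the test. Without NZM2328 female replicate 4 the adjusted p of Tlr7 by edgeR was 0.0329, and without male replicate 2 that of Rad21 was 0.0582. Of 39 Xist RNA interactors and X-inactivation factors, 12 fell and 27 did not pass the test (13 lower adjusted over the list alone), among them Eed, a Polycomb gene (-0.40, SE 0.08), Rlim, a ubiquitin ligase of X inactivation (-0.27, SE 0.05), Smc3 (-0.27, SE 0.05) and Rad21 (-0.23, SE 0.06), which fell. The Xist interactor list had a camera adjusted p of 0.00169, and adjusted p = 0.242 with an estimated correlation. The macrophage and monocyte markers were higher by a median of 4.15 beside these lists.

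**Figure D4:**
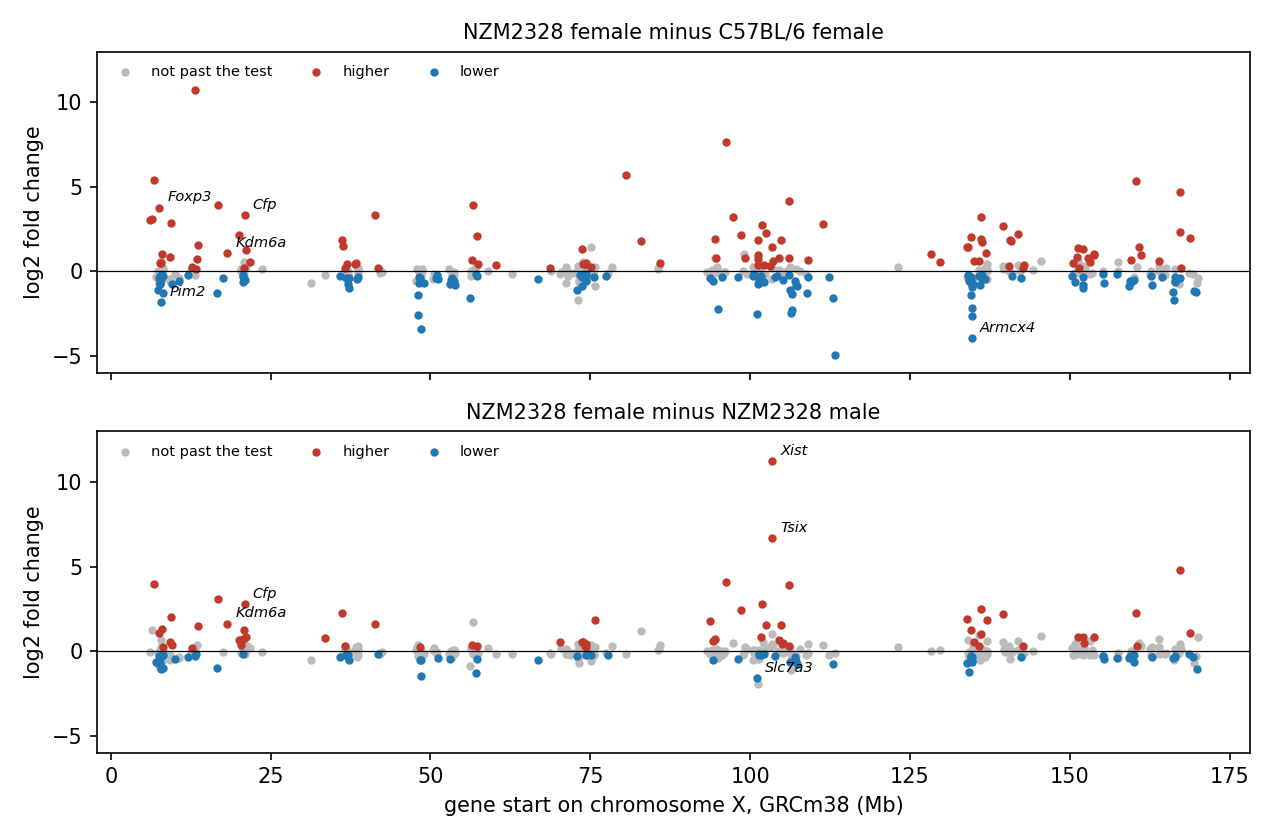
Log2 fold change of the 442 X-linked genes with a position, by gene start on chromosome X (GRCm38, megabases), in NZM2328 females against wild-type females (top) and against NZM2328 males (bottom); red points were higher and blue points lower at adjusted p under 0.05. Xist, at a log2 fold change of 11.24, and Tsix, at 6.69, were the highest X-linked genes against males. Tsix shares 34.4% of its 31-base sequences with Xist, so its value is uncertain.

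Both comparisons share the NZM2328 female libraries. In both, 1443 genes were higher in NZM2328 females, where independent lists would share 590, and 926 were lower, where independent lists would share 399. Another 323 genes changed in opposite directions, where independent lists would share 974. Across genes, which are not independent replicates, the fold changes of the comparisons had a correlation of 0.518 and a covariance of 0.616. In 20 simulations of unchanged groups sharing those libraries the mean correlation was 0.370, the mean covariance 0.0281, and no gene was shared. No gene was changed in these simulations, so the lack of shared genes was set by their design. With the female libraries split into 2 and 3, the mean over 20 splits was 1089 genes higher and 589 lower in both, with a covariance of 0.583. X-linked genes made up 40 of the genes higher in both and 53 of those lower in both.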

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

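The tests of a library far from the others of its group followed a rule set before the data were examined, and the tests of technical explanations were chosen only after the result was seen, except the difference between pseudogenes sharing much and little sequence, the pairs of all genes, and the bound for the interferon-stimulated genes with a covariate, which was set before that value was seen although the covariate itself was chosen after seeing the data.

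Among 147 named genes, 5 had a library of the NZM2328 females far from the other 4 (gap over range above 0.71), where chance gives about 1 in 20. Htatip2 was at 0.278 CPM in replicate 2 and 0 in the others (ratio 1), and Rbm44 at 0.605 CPM in replicate 5 and 0 to 0.0851 in the others (0.859). Bst2 was at 113.8 CPM in replicate 2 and 138.7 to 142.2 in the others (0.875). Tcrg-C4 was at 5.43 CPM in replicate 1 and 8.82 to 10.1 in the others (0.727), and Itm2a at 25.07 CPM in replicate 4 and 24.9 to 24.95 in the others (0.721).

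The macrophage, monocyte and neutrophil markers were higher in NZM2328 females than in males, although the cells were negatively selected. A lower share of T cells would raise the markers of other cells alike only if the make-up of those cells stayed the same. The median of the macrophage and monocyte markers lay 3.49 above that of the B cell markers, beyond the sum of the SDs over members (1.57 and 0.932). That is a spread over genes and not over libraries. A lower share of T cells with a changed make-up of the other cells stays open. Macrophages, monocytes and neutrophils among the cultured cells are a candidate source: within groups the macrophage and monocyte markers had a mean pairwise correlation of 0.587, above all 10000 random lists matched on expression (median 0.00852), and Lyz2 reached 236 ± 86.1 CPM. Whether such cells came from the mice, the selection or the culture was not tested, and sex stays open as an untested explanation.

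Interferon-stimulated genes were higher in NZM2328 males than in wild-type females (43 of 46 called higher by edgeR, median 1.265). In NZM2328 females 34 of 46 were called higher again than in males, 1 was lower and 11 did not pass the test (adjusted p = 0.147 by camera with an estimated correlation). Scaled by the macrophage markers alone, RNA of macrophages would not bring the first difference. Males had 1.44% of the macrophage marker excess of the females, and the genes lay a median of 1.221 above what that share would bring (quartiles 0.758 to 1.92, 45 of 46 above). This takes such cells to carry as much interferon-stimulated RNA per marker in males as in females, which was not tested. Neutrophil markers did not enter, and the macrophage markers were higher in males than in wild type by a median of 0.83. For females against males, RNA of macrophages and neutrophils cannot be told apart from other explanations. With the macrophage marker level as a covariate the median went from 0.622 to 0.695 (0.316 to 0.835 without 1 library, jackknife SE 0.408), 96.0% of the variance of that level lies between groups, and 0 of these genes were called by edgeR, as the median SE of their fold changes went from 0.124 to 0.440. The full value and the lowest lie above the bound set beforehand, 0.5 times the unadjusted median, but both by less than the jackknife SE; a margin of 2 such SE was asked of the full value only after it was seen, and age and sex stay open as untested.

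Genes near 0 in 1 female group and at 5 CPM or more in the other numbered 165, of which 140 were on in NZM2328 females, and 10 of these 140 were among the 68 tested markers of cell types other than T cells (odds ratio 17.29, interval 7.71 to 35.1, Fisher's exact p = 2.17e-09), each under 5 CPM in NZM2328 males. RNA of such cells may account for part of these 140, and sequence shared with near-identical genes for part of the 165. Of the 156 among the 165 that had a value of shared sequence, 31.4% shared at least 50% of their 31-base sequences against 6.64% of other genes (odds ratio 6.433, interval 4.46 to 9.17, Fisher's exact p = 3.82e-20). A strain variant against the reference stays open, since 35 of the 49 sharing genes (71.4%, exact interval 56.7 to 83.4) and 79 of all 165 (47.9%, 40.1 to 55.8) had the same state in NZM2328 males; the intervals were added to this reading after the values were seen. Processed pseudogenes summed to 9279 to 10024 counts per 1e+06 in wild type, 12856 to 13814 in NZM2328 females and 14641 to 14969 in males, a pattern reworded after its first test: pseudogenes sharing much sequence had a median fold change differing by -0.486 from those sharing little (-1.49 to 0.195, permutation p = 0.188), and of -0.0643 in males against wild type (sign test p = 0.154), which leaves both explanations open. Reads moving between a gene and its copy would send such pairs opposite ways, and 24.7% of 85 pseudogene pairs and 25% of 204 pairs of all genes did, against medians of 41.8% and 46.2% in random pairings.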

How the results depend on the processing

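The macrophage marker covariate, the restriction to genes with little shared sequence and the escape list without Xist were chosen only after the data were seen; all other tests here were planned. Across DESeq2, limma-voom, other scalings, filterByExpr, no filter, only the groups compared and the replicate block, the counts of changed genes stayed within 1.5 times their value, and under 2 other scalings the percent higher among changed genes was 51.2 to 54.7 against wild type and 55.0 to 62.6 against males. With the covariate, 298 genes (4 X-linked) were called against wild type, 3 (2 X-linked) against males and 1 in both; 96.0% of the covariate's variance lies between groups, and calls ended as the median SE over genes tested went from 0.117 to 0.503 and from 0.116 to 0.440, while the median absolute log2 fold change went from 0.35 to 0.54 and from 0.20 to 0.35. With an absolute log2 fold change above 1 there were 2513 (78 X-linked), 1053 (37 X-linked) and 813, and at adjusted p under 0.01 there were 1920 (72 X-linked) against males and 1341 in both; both settings raise the threshold. The X-linked minus autosomal difference against wild type, -0.0664, passed the 0.05 threshold with limma's fry, which does not compare the set with other genes. It was -0.0964, past the same threshold by camera, among genes with a mean CPM of at least 10. With an estimated correlation 0 of 33 lists held against wild type (16 with the preset correlation of camera) and 1, the Y-linked genes, against males (20 with the preset). The odds ratio of X-linked genes among lower genes turned without a filter on low counts, to 0.820 (Fisher's exact p = 0.0337) against wild type and 0.995 (p = 1) against males, with 24125 genes tested; with the covariate it turned to 57.26 (p = 0.00336) among higher genes and 0 (p = 1) among lower genes against males, from 3 calls. Among lower genes it was 1.262 against wild type (exact p = 0.0331) and 1.347 against males (exact p = 0.0545) with the replicate block, and 1.268 against wild type at adjusted p under 0.01 (exact p = 0.0443). Among higher genes it was 0.291 against wild type with the covariate (exact p = 0.0705) and 0.659 against males without a filter (exact p = 0.0012). The cause of these changes was not tested.

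Leaving out each library in turn gave 6496 to 7151 changed genes against wild type (204 to 229 X-linked), 2380 to 3585 against males (93 to 138 X-linked), 1698 to 2400 in both, differences of -0.0964 to -0.0584 and -0.0469 to -0.0185 for X-linked minus autosomal genes, 15 to 17 and 17 to 21 lists, and odds ratios of 0.655 to 0.744 and 1.122 to 1.303 against wild type (past 0.05 without wild-type replicate 4, exact p = 0.0157) and 0.875 to 0.993 and 1.363 to 1.641 against males. Of 190 fold changes of named genes, 190 kept their direction and side of the threshold with DESeq2, 188 with limma-voom and with the replicate block, and 189 without a filter. With the block, Fcer2a and Cd40lg missed the threshold against males by edgeR, the B cell and erythroid lists passed camera against wild type, and the apoptosis, mitochondrial and plasma cell lists passed it against males; apart from the odds ratios given above, it changed no other call. Of 66 list tests, 57 kept their side of the threshold without a filter and 9 passed camera that had not: the Xist interactor, stress response, B cell, erythroid and pan T cell lists against wild type, and the oxidative phosphorylation, apoptosis, mitochondrial and plasma cell lists against males. The escape list kept its side of the threshold without Xist in both comparisons. The 8 same-numbered pairs had correlations of -0.0358 to 0.0744, none over 0.1, so the numbers pair no libraries. Genes at few counts limit the folds against wild type, and the simulated recovery was 50.7% and 56.7% at 1.5-fold.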

Other observations

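The tests of 25 gene families were chosen after values had been seen; the other splits of the libraries were planned. Against wild type, ribosomal protein genes were lower in NZM2328 females (1 rose, 72 fell and 7 did not pass the test of 80, median -0.69), and so were cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNA with amino acids (14 fell and 3 did not pass the test of 17, median -0.57), with Aars at 236 ± 14 against 429.7 ± 18.8 CPM. Camera gave adjusted p = 1.68e-27 and 2.02e-06 over the families, and adjusted p = 0.190 and 0.400 with an estimated correlation. Against males, 53 ribosomal protein genes and 15 synthetase genes fell (medians -0.21 and -0.31, camera adjusted p = 5.84e-16 and 3.06e-08, and adjusted p = 0.249 and 0.324 with an estimated correlation). Processed pseudogenes named after ribosomal protein genes went both ways. Rpl3-ps1 was at 0.330 CPM in wild type and 576 in NZM2328 females, and Rpl19-ps11 at 100 and 0. The division of reads between such copies cannot be checked, and the fit with little shared sequence left ribosomal protein genes out, so their values are uncertain. The macrophage and monocyte markers were higher by medians of 4.99 and 4.15 beside these families.

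Chemokine ligand genes were higher in NZM2328 females than in wild type (16 rose and 2 did not pass the test of 18, median 3.46, camera adjusted p = 2.40e-05, and adjusted p = 0.400 with an estimated correlation). Ccl22, a ligand of Ccr4, was at 672 ± 147 CPM against 39.8 ± 1.29 in wild type and 318 ± 64.0 in males, and Cxcl9, an interferon-gamma-induced ligand of Cxcr3, at 98.2 ± 42.1, 1.37 ± 0.521 and 24.8 ± 7.13 CPM. Against males, 14 rose, 2 fell and 2 did not pass the test of 18 (median 2.15, camera adjusted p = 5.42e-05, and adjusted p = 0.416 with an estimated correlation). The genes that fell were Ccl3 and Ccl4 (log2 fold changes of -0.66 and -0.81), and among those that rose were Ccl6 and Ccl9, which myeloid cells express (5.43 and 4.34). Of 18 T cell receptor beta V segments, 6 rose, 10 fell and 2 did not pass the test against wild type (camera adjusted p = 0.0736), with Trbv3 at 0.296 ± 0.202 against 7.80 ± 0.290 CPM and 0.509 ± 0.196 in males. Macrophage and monocyte markers were higher by medians of 4.99 and 4.15 in these contrasts.

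Other splits of the libraries into groups of the same sizes bear on whether a chance arrangement of the libraries gives such results. For the genes changed against wild type (7340) 1 of 56 splits was as large, the real one, with the highest other at 1. Against males (3543) it was likewise 1 of 56, with the highest other at 12. The X-linked genes changed (233 and 135, 1 of 56 each, highest other 0) are part of these counts. Every other split mixes libraries of both groups, which widens the spread within groups and lowers the calls. Splits also cannot tell a batch that follows the groups from the groups themselves. For the genes changed in both (2369), 1 of 100 regroupings gave as many, the highest other 4. Those regroupings mix all groups and so break both lists of called genes at once. They cannot tell whether 2 such lists overlap by chance or through the shared female libraries. For the X-linked minus autosomal difference (-0.0664 and -0.0410) 2 of 56 splits were as large in each comparison, a share under 0.05, but the other split was larger than the real one (0.0836 and 0.0446 in absolute size) and camera did not separate the difference from 0, so chance is not firmly excluded. For the lists past the test against males (20), 2 of 56 splits gave as many, the highest other also 20, and 1 list held with an estimated correlation, so it is not firmly excluded there either. For the lists past the test against wild type (16), 14 of 56 splits gave as many, up to 20, so chance is not excluded.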
